A study of Homo sapiens with 24 samples.

How the data were processed

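RNA of C3A cells exposed for 2 h to 8 compounds was measured against control RNA on 24 two-colour arrays (Agilent SurePrint G3 Human Gene Expression), 3 per compound. Per the labels, cells were preincubated for 24 h, 6 wells were pooled per sample, 0.1% DMSO was the solvent control, treatments and controls had 3 biological replicates, and reverse transcription used random primers. The label field of each sample gives the exposed RNA as Cy5 and the control RNA as Cy3 on all 24 arrays, so a positive ratio means more RNA in exposed cells. The labelling protocol also says that all replicates of a treatment carried one dye and that each dye had its own DMSO control, which leaves open whether the control RNA was the same on every array. The labels give no concentrations, and they do not spell out PCP and TCP.

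The authors deposited scanner output of Feature Extraction 10.7.3.1, per the file headers, with an intensity per spot and channel (mean signal and median background, linear scale, not normalized), the software's processed signals (also an intensity, background-subtracted and dye-normalized per the file headers) and its own log10 ratio of Cy5 over Cy3. A second table deposited by the authors holds a score per spot and array (62976 spots), whose scale is not given in the sources used here. Its column medians were 0 on all 24 arrays, and 42405 non-control probes had a spot with a nonzero value. Over these the medians lay between -0.0151 and 0.0246. Across the kept genes each column correlated at 0.976 to 0.993 with the array's log2 ratio and at 0.928 to 0.974 with its log10 ratio divided by its error, and at least 90.6% of probes had the sign of the scanner's ratio. The slope on the log2 ratio differed between arrays (2.80 to 4.06), so the direction and centring on 0 are known and the scale is not. It served only as an alternative.

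Backgrounds were corrected with normexp (offset 50), and log2(Cy5/Cy3) was normalized within arrays by loess, with weight 0 for control spots and for spots marked as outliers by the scanner software (430 to 800 per array), which were then left out. No spot was saturated. Of 42405 probes, 23517 were kept, those well above background in a channel on all 3 arrays of at least 1 compound. Spots of a probe were averaged, and a gene name was represented by its brightest probe, which left 18347 genes. Of these 78% had 1 probe, 4031 had several, and 1665 had probes of opposite sign. Names are those of the array design (header annotation hg19); 13028 (71%) matched a transcript accession of the reference table, where 1670 current symbols differ, and the file's names were kept. Current symbols of genes named here are CCN1 for CYR61, CCN2 for CTGF, ESS2 for DGCR14, GAREM1 for FAM59A, GCNA for ACRC, CIMIP2A for FAM166A, MYCL for MYCL1 and RNA5-8SN5 for RN5-8S1. Coordinates are not given, because none were assigned to these genes here.

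The log ratios were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with a mean per compound over all 24 arrays and no block. Each mean was tested against 0 and against the mean of the other 7 compounds, and FCCP minus CCCP, Chloro-Aniline minus Aniline, PCP minus TCP and the mean of the 8 were tested in the same fit. Calls are at a Benjamini-Hochberg adjusted p under 0.05. The ratio against control has no dye swap behind it. Where the control signal was not well above background on all 3 arrays of a compound, the fold is given as a lower bound: the mean of the bright channel over the mean of, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background, after loess and Aquantile; such bounds stay open to dye bias. The single channels after that normalization gave the F-tests of Cy3 and Cy5.

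Replicate numbers 1, 2 and 3 coincide with slides 1, 2 and 3, scanned as scans 1, 2 and 3. Each slide holds all 8 compounds, so results are also given with the slide as block and within each slide. A compound lay at the same array position on each slide, so neither can tell compound and position apart.

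The lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. The 20 lists hold 363 genes, 319 of them measured: immediate early genes, ATF4 integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2 targets, aryl hydrocarbon receptor targets, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, gluconeogenesis and fasting, p53 targets, NF-kappaB and inflammatory genes, PXR and CAR drug metabolism, hepatocyte markers, markers of other liver cell types, metallothioneins, thyroid hormone targets, clock genes and cell cycle. Each was tested with camera (preset correlation 0.01) on a compound against the other 7, adjusted over all 160 tests; some genes, such as ATF3, DDIT4 and GDF15, stand in several lists. A median of 33 lists passed in regrouped arrays, so the estimated correlation is given beside each call. Genes named for a compound passed both tests in the same direction, with all 3 arrays on that side of 0 and of the other compounds' mean, and were the 12 highest and 12 lowest by the difference from the other compounds; 6 and 6 were taken for a pair, and 8 and 8 with the same sign on all 24 arrays for the mean of the 8. For FCCP minus CCCP, where no gene passed, the 4 highest and 4 lowest by the moderated statistic are given as values. Names that are only identifiers (5827 of the genes) were counted but not named. Of a list past its test, up to 4 members were examples.

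RASL10A (6OH-BDE90), CYP1B1 (Aniline) and RNU4ATAC (CCCP) were also taken by the rule; they were not well above background in exposed cells, at least 1.188-fold, 1.016-fold and 1.08-fold lower than control. CHRNA10 (-0.50 ± 0.14 over control, SD, n = 3, exposed signal well above background on 2 of 3 arrays) and LAG3 (-0.42 ± 0.30) complete the Chloro-Aniline genes.

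The fit was tested on simulated data with known changes in the 18347 genes: against control 86% of changes of 0.5 log2 and 100% of those of 1, 2 and 3 were recovered, against the other compounds 82% and 100%, and for the pair Chloro-Aniline minus Aniline 60%, 94%, 100% and 100%, with 4.46%, 6.83% and 3.28% of the calls false. Alternatives were no background correction, median centring, the scanner software's processed signals, no filter or a stricter one, the mean over probes, the authors' processed values, the replicate number as block, only the arrays of a comparison, array weights, Cy5 alone, Ethylenglycol as the reference, a fold of at least 2, an estimated correlation and each array left out. Leaving out 4 arrays together was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.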

Results

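C3A cells, a human liver cell line derived from HepG2, were exposed for 2 h to 8 compounds, and their RNA was compared with RNA of control cells on 24 arrays with 2 dyes. Each compound had 3 arrays: Ethylenglycol, 6OH-BDE90, Chloro-Aniline, Aniline, CCCP, PCP, FCCP and TCP. Each array gave a ratio of exposed (Cy5) over control (Cy3) signal per gene, given here on the log2 scale as mean ± SD over 3 arrays (n = 3) unless an SE is named. Between 33979 and 36972 of the 58717 non-control spots stood well above background in Cy3 and between 30770 and 35043 in Cy5, and the number of arrays limits the precision. The fit covered 18347 genes. The labels gave no concentrations, so a difference between compounds can be one of dose. Each compound was tested against its control channel and the mean of the other 7 (below, the other compounds), where a probe's dye effect cancels. Since no dye was swapped, a ratio against control holds any dye effect of its probe and leaves out the spread of the control cells.

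Among the genes with the same sign on all 24 arrays, DDIT3, ATF3, GADD45B and CHAC1 had the highest mean ratios over the 8 exposures, which differed in their responses. In that mean, DDIT3 (a transcription factor of the integrated stress response) was raised by 2.89 ± 0.08 on the log2 scale (SE), ATF3 (a stress-induced transcription factor) by 2.80 ± 0.06, GADD45B by 2.63 ± 0.08 and CHAC1 (a glutathione-degrading enzyme induced by ATF4) by 2.55 ± 0.06. FOS (2.45 ± 0.11), FOSB (2.28 ± 0.08) and DDIT4 (an inhibitor of mTORC1 signalling, 2.26 ± 0.04) followed. ARRDC3 was also higher, but its control signal stood well above background on only 6 of the 24 arrays, so its size is not given. Of the genes with the same sign on all 24 arrays, the lowest were HHEX (a homeobox factor of liver development, -1.22 ± 0.04), HSPA12A (-1.19 ± 0.07), DDX3X (an RNA helicase, -1.14 ± 0.09), GLYCTK (glycerate kinase, -1.09 ± 0.02) and ABCD3 (a peroxisomal transporter, -0.96 ± 0.05), with TAF15 (-0.93 ± 0.22), RBM3 (-0.83 ± 0.05) and ARHGEF3 (-0.82 ± 0.07). TAF15 stood at -2.82 or lower on 5 of the 24 arrays, with a median of -0.35 on the rest. Its mean was -0.60 without 4 arrays that were chosen after seeing the data (FCCP replicate 1, TCP replicate 1, 6OH-BDE90 replicate 2 and Chloro-Aniline replicate 1). All 16 had the same sign on all 24 arrays, with adjusted p between 1.7e-20 (DDIT4) and 0.00074 (TAF15) in limma. The mean of the 8 passed the test for 12210 genes, 6583 higher and 5627 lower, of which 66 changed by at least 2-fold. The share of higher calls was 53.9% and rose to 85.4% when arrays were median-centred in place of loess; it was 47.9% with the scanner software's processed signals and 48.6% with no background correction. Of the 66 genes 64 differed between compounds. FOS, for example, was at 0.14 ± 0.07 (SD, n = 3) over control with Ethylenglycol. This mean also holds dye effects and the control RNA.

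Ethylenglycol left most immediate early genes, which the other exposures raised, at or below the control level. MYC (a growth-promoting transcription factor) fell by 3.36 ± 0.13 on the log2 scale on exposure, and its ratio lay -3.40 ± 0.11 (SE) from the other 7 compounds (adjusted p = 3.5e-15, limma). DUSP1, a phosphatase that switches off MAP kinases, was at -0.44 ± 0.17 over control and differed from the other compounds by -3.61 ± 0.15 (SE, adjusted p = 4.4e-13). DUSP6 (an ERK phosphatase, -2.02 ± 0.05 over control), SOX9 (-1.88 ± 0.21), PLK3 (a stress-responsive kinase, -1.81 ± 0.11), and NR0B2 (a repressor of bile acid synthesis, -1.30 ± 0.04) fell. GDF15 (a stress-induced cytokine, -1.11 ± 0.09), JUN (-0.96 ± 0.27), CYR61 (-0.89 ± 0.27), RASD1 (-0.84 ± 0.04), ID2 (-0.82 ± 0.24) and ZFP36 (-0.76 ± 0.32) also fell. Each of these differed from the other compounds by -2.09 or more. Among genes that rose, FAM90A1 and FAM90A7 had a control signal not well above background (at least 3.305-fold and at least 2.215-fold over control). DGCR14 (1.41 ± 0.25), ADAM8 (a metalloprotease, 1.38 ± 0.36), MAN1C1 (a Golgi mannosidase, 1.23 ± 0.15), LAG3 (1.09 ± 0.18), and PRDM12 (0.94 ± 0.17) rose. So did the small RNAs SNORA62 (1.03 ± 0.26) and SCARNA12 (0.70 ± 0.26), and ND6 of the mitochondrial genome (0.58 ± 0.24). TXNIP, a glucose-responsive binding partner of thioredoxin, and its relative ARRDC4 rose by 1.23 ± 0.16 and 1.33 ± 0.14.

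Of 23 immediate early genes measured, 22 were lower with Ethylenglycol than with the other compounds (23 adjusted over the list alone). Against control 12 fell and 4 rose. The median difference of this list was -1.47. Camera gave adjusted p = 2.5e-29, and adjusted p = 0.0024 with an estimated correlation. Within slides 1, 2 and 3 the median was -1.65, -1.46 and -1.64 (adjusted p = 1.3e-30 with the slide as block). Of 25 targets of ATF4, the transcription factor of the integrated stress response, 13 were lower than with the other compounds (14 adjusted over the list alone). The list had adjusted p = 4.5e-11, but adjusted p = 0.092 with an estimated correlation. Yet 13 of the 25 rose against control and 1 fell, the former including ATF3 (1.03 ± 0.17). Of 22 p53 targets, 12 were lower (14 adjusted over the list alone), such as GADD45A, which lay -1.09 ± 0.12 (SE) from the other compounds. The list as a whole had adjusted p = 5e-09, and adjusted p = 0.12 with an estimated correlation. The heat shock list was lower (7 of 16 genes, 9 lower and 1 higher adjusted over the list alone, HSPA8 among the lower ones), while over control 5 rose and 2 fell. For this list camera gave adjusted p = 0.0027, and adjusted p = 0.43 with an estimated correlation. Inflammatory genes of the NF-kappaB list were lower as well (5 of 12 lower and 1 higher, 7 and 1 adjusted over the list alone, with CCL20 at -1.02 ± 0.12, SE), with 3 that rose and 2 that fell over control. The camera test gave adjusted p = 0.0064, and adjusted p = 0.48 with an estimated correlation. The hypoxia list was lower (6 of 23 genes, 9 lower and 1 higher adjusted over the list alone, with ERRFI1 at -1.67 ± 0.13, SE), while over control 8 rose and 3 fell. As a set they had adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation. Targets of the aryl hydrocarbon receptor were lower (2 of 7, also adjusted over the list alone: TIPARP and CYP1A1, the latter at -2.66 ± 0.15 over control). Over the whole list camera gave adjusted p = 0.033, and adjusted p = 0.43 with an estimated correlation. Nuclear subunits of oxidative phosphorylation lay slightly higher, by a median of 0.07 (5 of 48 higher, 3 adjusted over the list alone). Tested as a list, they had adjusted p = 0.013, and adjusted p = 0.26 with an estimated correlation. The metallothionein list passed as lower (adjusted p = 0.04, and adjusted p = 0.71 with an estimated correlation) with 0 of 11 members called either way in limma, also adjusted over the list alone.

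Against control, 5808 genes passed with Ethylenglycol (2909 higher, 2899 lower; 116 by at least 2-fold). In all, 2967 differed from the other compounds (1113 higher, 1854 lower; 3325 with the slide as block). Of these genes, selected by the test, 2961 kept their direction within each of the 3 slides, as did 50.8% of all genes. The share of higher calls against the other compounds was 37.5%, 23.3% with median centring and 50.7% with the scanner software's own processed signals. Against control it was 50.1%, 87.0% with median centring and 43.9% with no background correction. Without replicate 2 the counts were 2834 against control and 1699 against the other compounds, and without replicate 1 the latter was 1946. All 24 genes named here passed without each array in turn. The list call of aryl hydrocarbon receptor targets ended without replicate 2 (adjusted p = 0.055) and that of the hypoxia list without replicate 1 (adjusted p = 0.079). So did those of oxidative phosphorylation without replicate 3 (adjusted p = 0.076) and metallothioneins without any 1 of them (adjusted p between 0.051 and 0.071).

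**Figure D1:**
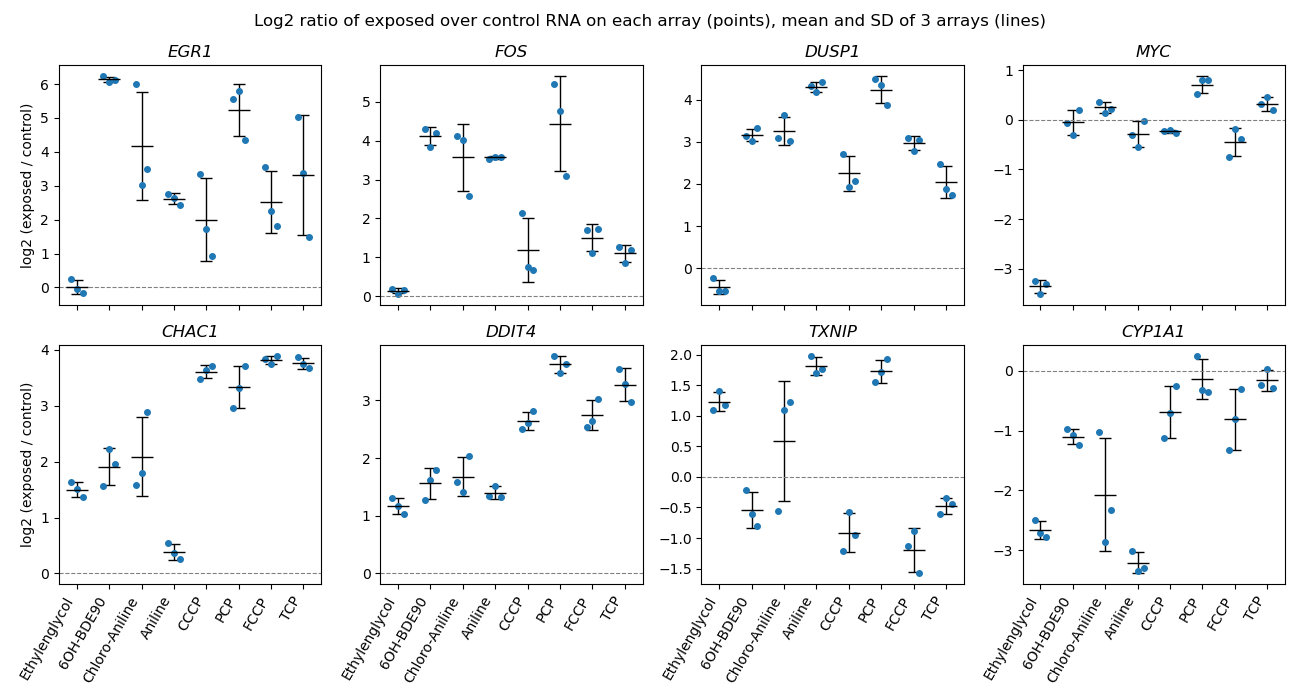
Log2 ratio of exposed over control RNA (vertical axes) for 8 genes in each of the 8 compounds (horizontal axes), chosen after their values were seen. Points are single arrays, with replicates 1 to 3 from left to right, and lines give the mean and SD of 3 arrays. DUSP1 lay at -0.44 with Ethylenglycol and between 2.04 and 4.31 with the other compounds, MYC fell by 3.36 with Ethylenglycol, and CHAC1 stood at 3.61, 3.82 and 3.76 with CCCP, FCCP and TCP.

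Immediate early genes lay higher with 6OH-BDE90 than with the other compounds. EGR1 rose by 6.14 ± 0.08 over control, 3.31 ± 0.56 (SE) above the other compounds (adjusted p = 0.0053, limma), and FOS rose by 4.12 ± 0.24, 1.90 ± 0.33 (SE) above them. EGR2 rose at least 7.944-fold from a control signal not well above background. EGR4 (2.60 ± 0.19), FOSB (3.28 ± 0.18), RASD1 (3.12 ± 0.16) and CYR61 (2.55 ± 0.02) rose. EDN1 rose by 1.05 ± 0.27, NPPB by 1.15 ± 0.40 and DUSP6 by 0.90 ± 0.06. The small RNAs RNU2-2 and SNORA26 rose by 1.79 ± 0.47 and 0.77 ± 0.47. The genes that fell moved less: FAM59A (-0.71 ± 0.06), ZBED3 (-0.65 ± 0.17), KRCC1 (-0.54 ± 0.11), ZNF280C (-0.52 ± 0.17) and the DNA exonuclease TREX1 (-0.51 ± 0.08). ANKRA2, TRIM52, ZNF266, CSRNP2, ZNF23 and ZNF200 lay between -0.71 and -0.36.

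Of 23 immediate early genes, 7 were higher with 6OH-BDE90 than with the other compounds (13 adjusted over the list alone) and 17 rose over control. The median difference was 0.49. The list as a whole had adjusted p = 2.5e-12, and adjusted p = 0.042 with an estimated correlation. Within the slides the median was 0.41, 0.42 and 0.59 (adjusted p = 1.7e-14 with the slide as block). ATF4 targets were lower than with the other compounds (10 of 25 lower and 1 higher, 15 and 1 adjusted over the list alone), while over control 12 rose and 0 fell. Camera gave adjusted p = 1.8e-12, but adjusted p = 0.071 with an estimated correlation. SESN2, a stress-induced inhibitor of mTORC1, lay -0.92 ± 0.13 (SE) and CTH, an enzyme of cysteine synthesis, -0.88 ± 0.11 (SE) from the other compounds. In the p53 list 2 of 22 genes were lower, SESN2 and BBC3 (3 adjusted over the list alone). The list had adjusted p = 2.1e-05, and adjusted p = 0.26 with an estimated correlation. Metallothioneins were higher as a list. Camera gave adjusted p = 0.0066, and adjusted p = 0.62 with an estimated correlation. None of the members passed against the other compounds (0 of 11, also adjusted over the list alone), while 10 of 11 rose over control, such as MT1G (2.94 ± 0.22). Glycolysis enzymes shifted by a median of 0.06 with 0 of 15 called, also adjusted over the list alone. The list had adjusted p = 0.041, and adjusted p = 0.49 with an estimated correlation. This call ended without replicate 2 (adjusted p = 0.14) or 3 (adjusted p = 0.064).

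For 6OH-BDE90, 5500 genes passed against control (2907 higher, 2593 lower; 88 by at least 2-fold) and 177 against the other compounds (72 higher, 105 lower; 276 with the slide as block). All 177, selected by the test, kept their direction within each slide, as did 40.7% of all genes. The shares of higher calls were 52.9% and 40.7%, and 85.8% and 12.6% with median centring. The first was 46.6% with the scanner software's processed signals, 49.4% in the authors' processed values and 46.4% with no background correction. Without replicates 1, 2 and 3 the count against the other compounds was 21, 16 and 39. Of the 24 genes named 20, 20 and 16 were no longer called, FOS and FOSB among them each time and EGR1 without replicates 1 and 2. Against control the count was 3593 without replicate 1 and 2453 without replicate 2. Replicate 2 correlated on average at 0.76 with the other 6OH-BDE90 arrays and at 0.826 with FCCP replicate 1, and without the 4 arrays named above 275 genes passed against the other compounds.

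With Chloro-Aniline, NF-kappaB genes and immediate early genes lay higher than with the other compounds (camera), but adjusted p = 0.18 and adjusted p = 0.092 with an estimated correlation. CXCL2, a neutrophil-attracting chemokine, rose at least 3.747-fold from a control signal not well above background. KLF6 rose by 2.37 ± 0.59, 1.31 ± 0.16 (SE) above the other compounds (adjusted p = 0.00035, limma). NFKBIA, the inhibitor of NF-kappaB, rose by 1.92 ± 1.09, FOS by 3.57 ± 0.86, CYR61 by 2.14 ± 0.64 and NUAK2 by 1.82 ± 0.48. Smaller rises were those of IER3 by 1.71 ± 0.21, CTGF by 1.35 ± 0.15, SAMD8 and NCOA7 by 1.18 ± 0.33 each, SPRY1 by 0.91 ± 0.77 and RNF43 by 0.48 ± 0.23. SCARNA13, a small Cajal body RNA, fell by 2.30 ± 0.60, and MAT2A, which makes S-adenosylmethionine, fell by 1.70 ± 0.19. NUFIP2 (-1.11 ± 0.52), SMAD4 (-0.89 ± 0.55), and XRCC2 (-0.83 ± 0.31) were also lower. HEXIM1 (an inhibitor of transcription elongation, -0.80 ± 0.32), PCF11 (-0.74 ± 0.37), SCARNA16 (-0.70 ± 0.44), OSGIN1 (-0.59 ± 0.22) and POLR2A (the largest subunit of RNA polymerase II, -0.47 ± 0.10) fell with them. POLR2A over control turned to 0.05 with median centring.

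The NF-kappaB list was higher in 5 of 12 genes (8 adjusted over the list alone) with a median difference of 0.40. For this list camera gave adjusted p = 1.1e-07, but adjusted p = 0.18 with an estimated correlation. This median was -0.07, 0.79 and 0.44 within slides 1, 2 and 3 (adjusted p = 2.5e-07 with the slide as block). Its members TNFAIP3 and BIRC3, which limit NF-kappaB signalling and apoptosis, lay 1.19 ± 0.25 and 0.69 ± 0.13 (SE) above the other compounds. Of 23 immediate early genes 9 were higher (13 higher and 1 lower adjusted over the list alone) and 19 rose over control. For this list camera gave adjusted p = 1.2e-08, and adjusted p = 0.092 with an estimated correlation. ATF4 targets lay lower than with the other compounds in 4 of 25 genes, DDIT4 and ASNS among them (10 adjusted over the list alone), while over control 16 rose and 0 fell. The camera test gave adjusted p = 1e-07, and adjusted p = 0.18 with an estimated correlation. Metallothioneins were lower as a list, with 0 of 11 members called and 2 lower adjusted over the list alone. The camera test gave adjusted p = 0.00028, and adjusted p = 0.49 with an estimated correlation. The aryl hydrocarbon receptor list was lower with 1 of 7 genes called, CYP1B1 at -0.92 ± 0.17 (SE; 2 adjusted over the list alone). Its adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation, came with a median of 0.14 within slide 1. The p53 list was higher in 3 of 22 genes, SESN1, GADD45A and BTG2 (4 adjusted over the list alone). Its adjusted p = 0.049, and adjusted p = 0.61 with an estimated correlation, came with a median of -0.11 within slide 1. Without replicate 3 the calls of these last 3 lists ended (adjusted p = 0.072, 0.073 and 0.75), as did those of the last 2 without replicate 2 (adjusted p = 0.14 and 0.17).

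With Chloro-Aniline 5028 genes passed against control (2776 higher, 2252 lower; 116 by at least 2-fold) and 528 against the other compounds (371 higher, 157 lower; 676 with the slide as block). Of these genes, selected by the test, 480 lay in the same direction within each slide, as did 36.3% of all genes; slide 1 correlated at 0.13 and 0.0789 with slides 2 and 3 across genes. The shares of higher calls were 55.2% and 70.3%, and 91.7% and 89.9% with median centring. Against control the share was 47.2% with the scanner software's processed signals, 47.9% in the authors' processed values and 49.5% with no background correction. Replicate 1 differed from replicates 2 and 3, with TXNIP at -0.55 against 1.09 and 1.22. Without replicate 1 the count against the other compounds was 1010, without replicate 2 it was 17, without replicate 3 it was 106 and without the 4 arrays it was 1206. CXCL2 and NFKBIA, for example, lost the call without replicate 2 (adjusted p = 0.14 and 0.17), as did 18 of the 24 genes named, against 3 and 12 without replicates 1 and 3. Against control 2893 and 3189 genes passed without replicates 2 and 3.

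Aniline raised GADD45B and the inducible HSP70 genes and lowered CYP1A1. GADD45B, a growth arrest gene, rose by 4.71 ± 0.15, 2.37 ± 0.23 (SE) above the other compounds (adjusted p = 6.9e-07, limma). DUSP1 (4.31 ± 0.12), NFKBIA (2.44 ± 0.18), TNFAIP3 (2.06 ± 0.24), PLK3 (2.00 ± 0.19), TXNIP (1.81 ± 0.15), MYCL1 (1.78 ± 0.12, control signal well above background on 2 of 3 arrays) and SPRY1 (1.19 ± 0.14) rose. ARRDC3 rose at least 8.824-fold from a control signal not well above background. The inducible HSP70 genes HSPA1B and HSPA1A rose by 2.60 ± 0.30 and 2.28 ± 0.31, and RN5-8S1, a ribosomal RNA, by 2.63 ± 0.55. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, fell by 3.21 ± 0.18 and lay -2.12 ± 0.24 (SE) from the other compounds (adjusted p = 4.3e-06). SCARNA13 (-2.66 ± 0.19), LRRC25 (-2.04 ± 0.04), the paraspeckle RNA NEAT1 (-1.55 ± 0.12), COX19 (-1.41 ± 0.08), and ZNF721 (-1.29 ± 0.30) fell with it. SERTAD2 (-1.25 ± 0.14), the heat sensor channel TRPV1 (-1.13 ± 0.19), the cytokine LIF (-1.05 ± 0.03), GRPEL2 (-1.02 ± 0.19) and TIPARP (-0.82 ± 0.25) were lower as well.

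ATF4 targets were lower with Aniline than with the other compounds in 15 of 25 genes (17 adjusted over the list alone), with CHAC1 at -2.47 ± 0.17 (SE) and ATF4 itself at -1.05 ± 0.08 (SE). Over control 13 rose and 3 fell. As a set they had adjusted p = 1.4e-12, but adjusted p = 0.071 with an estimated correlation. The median was -0.58, and -0.41, -0.66 and -0.63 within the slides (adjusted p = 1.1e-13 with the slide as block). Heat shock genes were higher in 4 of 16 (7 adjusted over the list alone), such as HSPA4L at 0.83 ± 0.13 (SE), and 13 rose over control. As a set they had adjusted p = 9.2e-05, and adjusted p = 0.35 with an estimated correlation. The NF-kappaB list was higher in 5 of 12 and lower in 1 (9 and 1 adjusted over the list alone), with IRF1, a transcription factor of the interferon response, at 1.06 ± 0.13 (SE). Over the whole list camera gave adjusted p = 3e-05, and adjusted p = 0.29 with an estimated correlation. Of 7 aryl hydrocarbon receptor targets, CYP1A1, TIPARP and CYP1B1 were lower (5 adjusted over the list alone). Tested as a list, they had adjusted p = 0.00038, and adjusted p = 0.2 with an estimated correlation. In the list of gluconeogenesis and fasting genes 4 of 8 were higher and 1 lower (also adjusted over the list alone). The list as a whole had adjusted p = 0.02, and adjusted p = 0.12 with an estimated correlation. PCK1, the first committed enzyme of gluconeogenesis, lay at 1.15 ± 0.22 (SE) and ANGPTL4 at 0.81 ± 0.12 (SE).

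Aniline gave 7352 calls against control (3469 higher, 3883 lower; 228 by at least 2-fold) and 2526 against the other compounds (702 higher, 1824 lower; 2791 with the slide as block). Of these genes, selected by the test, 2516 kept their direction within each slide, as did 46.6% of all genes. Higher calls made up 47.2% against control, and 83.5% with median centring. Without replicate 2 the counts were 4654 and 1300, and 1591 against the other compounds without replicate 1. HSPA1A lost its call against the other compounds without each array in turn, HSPA1B without replicate 2 or 3 and RN5-8S1 without replicate 1 or 2.

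CCCP, an uncoupler of oxidative phosphorylation, raised ATF4 targets. CHAC1 rose by 3.61 ± 0.12, 1.21 ± 0.17 (SE) above the other compounds (adjusted p = 0.0015, limma), and CEBPB, a transcription factor of stress and acute phase responses, rose by 2.32 ± 0.02, 0.92 ± 0.11 (SE) above them (adjusted p = 0.00017). SLC7A11, the cystine transporter subunit, rose by 1.60 ± 0.48, the secreted protein gene STC2 by 1.33 ± 0.14, and ACRC by 1.28 ± 0.19. Smaller rises were those of GRPEL2 by 1.14 ± 0.21, CSRNP2 by 1.06 ± 0.21, PPP1R10 by 0.78 ± 0.06, ZNF529 by 0.76 ± 0.11, HEXIM1 by 0.74 ± 0.19, PHLDA1 by 0.58 ± 0.22 and COX19 by 0.52 ± 0.25. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 1.33 ± 0.27, TXNIP fell by 0.91 ± 0.32 and RNU2-2 fell by 0.85 ± 0.39. The tubulin genes TUBB4B (-0.90 ± 0.39), TUBB6 (-0.87 ± 0.27), TUBB8 (-0.72 ± 0.26) and TUBA4A (-0.58 ± 0.22) fell as well, as did ISX (-0.81 ± 0.17), FAM166A (-0.57 ± 0.36), EDN1 (-0.51 ± 0.22) and the chemokine CCL20 (-0.40 ± 0.11).

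Of 25 ATF4 targets, 9 were higher with CCCP than with the other compounds (14 adjusted over the list alone) and 22 rose over control. The median difference was 0.40 (camera adjusted p = 6.3e-18, and adjusted p = 0.03 with an estimated correlation), and 0.32, 0.39 and 0.39 within the slides (adjusted p = 1.5e-19 with the slide as block). Immediate early genes were lower than with the other compounds in 6 of 23 (12 lower and 1 higher adjusted over the list alone). Camera gave adjusted p = 2e-07, and adjusted p = 0.12 with an estimated correlation. Yet 14 rose over control and 1 fell. FOS, at 1.18 ± 0.82 over control, lay -1.45 ± 0.33 (SE) from the other compounds. NF-kappaB genes were lower in 3 of 12 (6 adjusted over the list alone), with TNFAIP3 at -1.21 ± 0.25 (SE). The list had adjusted p = 5.4e-07, and adjusted p = 0.2 with an estimated correlation. The p53 list was higher with 1 of 22 genes called, SESN2 (1 higher and 1 lower adjusted over the list alone). For this list camera gave adjusted p = 0.041, and adjusted p = 0.59 with an estimated correlation. Aryl hydrocarbon receptor targets were higher as a list with 0 of 7 called and 1 adjusted over the list alone, while over control 2 rose and 4 fell. Over the whole list camera gave adjusted p = 0.017, and adjusted p = 0.39 with an estimated correlation. Endoplasmic reticulum chaperones shifted by a median of 0.10 with 0 of 16 called, also adjusted over the list alone. Tested as a list, they had adjusted p = 0.04, and adjusted p = 0.59 with an estimated correlation. The calls of these last 3 lists ended without replicate 3 (adjusted p = 0.078, 0.089 and 0.4), and those of the p53 and aryl hydrocarbon receptor lists without replicate 2 (adjusted p = 0.1 and 0.053).

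CCCP gave 3377 calls against control (1965 higher, 1412 lower; 76 by at least 2-fold) and 153 against the other compounds (52 of them lower; 217 with the slide as block). All 153, selected by the test, kept their direction within each slide, as did 39.2% of all genes. Higher calls made up 58.2% and 66.0%, and 93.3% and 82.3% with median centring. Against control they were 48.8% with the scanner software's processed signals and 49.3% in the authors' processed values. Without replicates 1, 2 and 3 the count against the other compounds was 74, 15 and 100, and 12, 19 and 9 of the 24 genes named lost their call. TUBB4B, TUBA4A and TUBB6 were lost without replicates 1 and 2 and TUBB8 without replicate 2. Against control 1793 and 2092 genes passed without replicates 1 and 2. Without the 4 arrays, 303 passed against the other compounds.

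PCP raised immediate early genes and metallothioneins, and the metallothionein list had adjusted p = 0.24 with an estimated correlation. GADD45B rose by 4.94 ± 0.23, 2.64 ± 0.23 (SE) above the other compounds (adjusted p = 1.3e-07, limma). EGR1 rose by 5.23 ± 0.77, FOS by 4.44 ± 1.22, RASD1 by 3.83 ± 0.89, ZFP36 (a factor of mRNA decay) by 3.13 ± 0.75, NEAT1 by 2.43 ± 0.85 and DUSP6 by 1.91 ± 0.32. The metallothionein genes, which encode metal-binding proteins, rose: MT1E by 3.34 ± 1.55, MT1M by 3.01 ± 1.15, MT2A by 3.00 ± 1.47, MT1L by 2.87 ± 1.35 and MT1B by 2.84 ± 1.45. SCARNA13 fell by 2.65 ± 0.11, SCARNA12 by 1.91 ± 0.22, SNORA26 by 1.29 ± 0.31 and SCARNA16 by 1.11 ± 0.10, all small RNAs of the nucleolus or Cajal bodies. SNORA12 fell as well (-2.54 ± 0.15), but its exposed signal was well above background on 1 of 3 arrays. DDX3X (-2.02 ± 0.29), PPP1R10 (-1.54 ± 0.08), and TNFRSF10D (a decoy receptor of TRAIL, -1.53 ± 0.65) also fell. DIDO1 (-1.52 ± 0.45), ND6 (-1.41 ± 0.09), HNRNPH3 (-1.38 ± 0.09) and CALU (-0.92 ± 0.19) did so too.

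With PCP 18 of 23 immediate early genes were higher than with the other compounds (19 adjusted over the list alone). The median difference was 1.32 (camera adjusted p = 1.2e-25, and adjusted p = 0.0024 with an estimated correlation), and 1.19, 1.41 and 0.96 within the slides (adjusted p = 1.1e-27 with the slide as block). Of 11 metallothionein genes 10 were higher (11 adjusted over the list alone) and 11 rose over control. Their median lay 1.96 above the other compounds. The list as a whole had adjusted p = 4.8e-10, but adjusted p = 0.24 with an estimated correlation. The median was 2.89, 1.29 and 1.31 within the slides (adjusted p = 2.5e-11 with the slide as block). The p53 list was higher in 7 of 22 (9 adjusted over the list alone), with GDF15 at 1.86 ± 0.16 and CDKN1A, a cell cycle inhibitor, at 0.96 ± 0.20 (SE). The camera test gave adjusted p = 1.8e-07, and adjusted p = 0.18 with an estimated correlation. ATF4 targets were higher in 6 of 25 (7 adjusted over the list alone), DDIT4 by 1.56 ± 0.13 (SE). As a set they had adjusted p = 0.00021, and adjusted p = 0.35 with an estimated correlation. The hypoxia list was higher in 6 of 23 (also adjusted over the list alone), with the vasodilator peptide gene ADM at 1.33 ± 0.15 (SE). Over the whole list camera gave adjusted p = 0.0031, and adjusted p = 0.35 with an estimated correlation. NF-kappaB genes were higher in 4 of 12 (also adjusted over the list alone), with CCL20 at 1.55 ± 0.12 (SE). Tested as a list, they had adjusted p = 0.0038, and adjusted p = 0.43 with an estimated correlation. Clock genes were higher in 4 of 12 (4 higher and 1 lower adjusted over the list alone), with the repressor NR1D1 at 1.29 ± 0.19 (SE). The list as a whole had adjusted p = 0.0055, and adjusted p = 0.095 with an estimated correlation. Cholesterol synthesis genes were higher in 4 of 21 (5 adjusted over the list alone), HSD17B7 by 1.08 ± 0.14 (SE). Camera gave adjusted p = 0.025, and adjusted p = 0.64 with an estimated correlation. Oxidative phosphorylation subunits were lower as a list (3 of 48 and 2 adjusted over the list alone, median -0.06). The list had adjusted p = 0.0032, and adjusted p = 0.19 with an estimated correlation. NRF2 targets were lower as a list (3 of 18, AKR1C1, AKR1B10 and TXN, also adjusted over the list alone). For this list camera gave adjusted p = 0.02, and adjusted p = 0.24 with an estimated correlation.

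PCP gave 5431 calls against control (3136 higher, 2295 lower; 227 by at least 2-fold) and 1462 against the other compounds (1111 higher, 351 lower; 1713 with the slide as block). Of these genes, selected by the test, 1449 lay in the same direction within each slide, as did 46.1% of all genes. Higher calls made up 57.7% and 76.0%, 92.0% and 90.1% with median centring, and 45.0% and 62.1% with the scanner software's processed signals. In the authors' processed values the share against control was 48.5%. Replicate 1 carried the highest metallothionein ratios (MT1E 5.13, against 2.39 and 2.50), and without it MT1E (adjusted p = 0.084), MT1M, MT2A, MT1L, MT1B, EGR1 (adjusted p = 0.076) and 4 genes that fell were no longer called against the other compounds. The metallothionein list still passed (adjusted p = 4.1e-05) and the cholesterol list did not (adjusted p = 0.53). Without replicates 2 and 3 the count against the other compounds was 650 and 864, and without replicate 2 EGR1, DIDO1, DDX3X and TNFRSF10D were lost. The NRF2 list (adjusted p = 0.066) and the ATF4 list (adjusted p = 0.12) lost their calls in that order.

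FCCP, an uncoupler whose phenyl ring carries a trifluoromethoxy group while that of CCCP carries a chlorine, raised ATF4 targets. CHAC1 rose by 3.82 ± 0.07, 1.45 ± 0.17 (SE) above the other compounds (adjusted p = 9.8e-05, limma). ATF3 rose by 3.67 ± 0.14, CEBPB by 2.44 ± 0.10, SERTAD1 by 2.20 ± 0.40, SLC7A11 by 1.87 ± 0.48, the co-chaperone DNAJB4 by 1.70 ± 0.26, AMOTL2 by 1.63 ± 0.09 and ACRC by 1.41 ± 0.46. FAM53C rose by 1.21 ± 0.44, POLR2A by 0.91 ± 0.14, HEXIM1 by 0.85 ± 0.23 and COX19 by 0.66 ± 0.36. SGK1, a kinase induced by serum and glucocorticoids, fell by 1.55 ± 0.31, TXNIP by 1.20 ± 0.36 and SPRY1 by 1.15 ± 0.34. The tubulins TUBB6 (-0.89 ± 0.23), TUBA1A (-0.84 ± 0.22) and TUBB4B (-0.71 ± 0.33) fell. Lower too were RNF43 (-0.63 ± 0.16), ZNF57 (-0.45 ± 0.11), PIM1 (-0.40 ± 0.15), RAB3A (-0.39 ± 0.22, exposed signal well above background on 1 of 3 arrays), CCL20 (-0.37 ± 0.24) and SPRY2 (-0.36 ± 0.14).

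Of 25 ATF4 targets 13 were higher with FCCP (14 adjusted over the list alone) and 22 rose over control. The median difference was 0.54 (camera adjusted p = 4.5e-19, and adjusted p = 0.028 with an estimated correlation), and 0.37, 0.50 and 0.61 within the slides (adjusted p = 1.3e-20 with the slide as block). The p53 list was higher in 5 of 22 (also adjusted over the list alone), with SESN2 at 0.73 ± 0.13 and the phosphatase PPM1D at 0.38 ± 0.09 (SE). The camera test gave adjusted p = 0.00031, and adjusted p = 0.35 with an estimated correlation. NF-kappaB genes were lower in 2 of 12 (4 adjusted over the list alone), CCL20 by -0.71 ± 0.12 (SE). As a set they had adjusted p = 5.7e-06, and adjusted p = 0.26 with an estimated correlation. Aryl hydrocarbon receptor targets were higher as a list with 0 of 7 called and 3 adjusted over the list alone, while over control 2 rose and 4 fell. Camera gave adjusted p = 0.023, and adjusted p = 0.41 with an estimated correlation. Their median was -0.03 within slide 1, and the call ended without replicate 2 (adjusted p = 0.15) or 3 (adjusted p = 0.17).

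FCCP gave 4535 calls against control (2519 higher, 2016 lower; 103 by at least 2-fold) and 359 against the other compounds (286 higher, 73 lower; 479 with the slide as block). These genes, selected by the test, all kept their direction within each slide. Of all genes 29.9% did so, and the slides correlated at -0.0721, 0.109 and 0.548 across genes (1 with 2, 1 with 3 and 2 with 3). Higher calls made up 55.6% against control, 93.4% with median centring, 46.1% with processed signals, 49.9% in the authors' values and 49.5% with no background correction. Without replicates 2 and 3 the count against the other compounds was 81 and 52, with 8 and 12 of the 24 genes named lost. Against control it was 2686 without replicate 1. Replicate 1 correlated on average at 0.514 with the other FCCP arrays and at 0.879 with TCP replicate 1, and without the 4 arrays 629 genes passed against the other compounds. TUBB6 and TUBA1A were lost without replicates 1 and 2, and TUBB4B without replicates 2 and 3.

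TCP raised ATF4 targets. CHAC1 rose by 3.76 ± 0.10, 1.38 ± 0.17 (SE) above the other compounds (adjusted p = 0.00022, limma), and DDIT4 rose by 3.27 ± 0.29, 1.15 ± 0.13 (SE) above them (adjusted p = 4.4e-05). CEBPB (2.40 ± 0.20), GDF15 (2.09 ± 0.73), SLC7A11 (1.75 ± 0.31), and TIPARP (1.53 ± 0.21) rose. HCAR3 (a receptor for hydroxylated fatty acids, 1.42 ± 0.04), DLX2 (1.30 ± 0.27), SOCS2 (a feedback inhibitor of cytokine signalling, 1.06 ± 0.53), SNAR-A3 (0.86 ± 0.29), COX19 (0.83 ± 0.20) and LMCD1 (0.80 ± 0.21) rose as well. The genes that fell moved less: NAPEPLD (-0.68 ± 0.19), the aldo-keto reductases AKR1B15 (-0.60 ± 0.14) and AKR1B10 (-0.45 ± 0.09), the mitotic kinesin KIF20A (-0.59 ± 0.16), and PSRC1 (-0.47 ± 0.19). RNF43, FAM72D, NUDT6, ZNF839, EID2B, KLLN (exposed signal well above background on 1 of 3 arrays) and the DNA methyltransferase DNMT3B (-0.32 ± 0.10) also fell.

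Of 25 ATF4 targets 16 were higher with TCP (21 adjusted over the list alone) and 24 rose over control. The median difference was 0.63 (camera adjusted p = 1.5e-32, and adjusted p = 0.0024 with an estimated correlation), and 0.76, 0.75 and 0.49 within the slides (adjusted p = 3.6e-34 with the slide as block). Of 7 aryl hydrocarbon receptor targets 4 were higher than with the other compounds (6 adjusted over the list alone), while over control 2 rose, 2 fell and the median was -0.16. CYP1A1 was higher by 1.36 ± 0.24, TIPARP by 1.05 ± 0.22, CYP1B1 by 0.96 ± 0.17 and AHRR, a repressor of the receptor, by 0.67 ± 0.15 (SE). Over the whole list camera gave adjusted p = 3.2e-07, but adjusted p = 0.071 with an estimated correlation. CYP1A1 itself stood at -0.16 ± 0.17 over control, and the list medians within the slides were 0.46, 0.64 and 0.86. Heat shock genes were lower as a list with 0 of 16 called and 8 adjusted over the list alone (4 rose and 0 fell over control). The list had adjusted p = 1.1e-05, and adjusted p = 0.28 with an estimated correlation. Immediate early genes shifted by a median of -0.07, with 3 of 23 lower and 1 higher (4 and 1 adjusted over the list alone), while over control 16 rose and 2 fell. Tested as a list, they had adjusted p = 0.013, and adjusted p = 0.43 with an estimated correlation. FOS and DUSP1 were among the lower ones. Glycolysis enzymes shifted by a median of -0.09 with 0 of 15 called and 1 adjusted over the list alone. For this list camera gave adjusted p = 0.0039, and adjusted p = 0.35 with an estimated correlation. NF-kappaB genes were lower as a list with 0 of 12 called, 1 higher and 2 lower adjusted over the list alone, and 3 that rose and 0 that fell over control (adjusted p = 0.041, adjusted p = 0.61 with an estimated correlation, and adjusted p = 0.055 with the slide as block). Without replicate 3 the immediate early (adjusted p = 0.39) and NF-kappaB (adjusted p = 0.24) calls ended.

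TCP gave 4615 calls against control (2545 higher, 2070 lower; 110 by at least 2-fold) and 296 against the other compounds (218 higher, 78 lower; 401 with the slide as block). These genes, selected by the test, all kept their direction within each slide. Of all genes 33.6% did so, and the slides correlated at 0.324, 0.1 and 0.465 across genes in the same order. Higher calls made up 55.1% against control, 93.7% with median centring, 45.1% with the scanner software's processed signals, 48.6% in the authors' values and 48.3% with no background correction. Without replicate 1, TCP lost 189 calls against the other compounds on balance, and 1674 were left against control. Without replicate 2, 64 were left against the other compounds. Of the 24 genes named 13, 16 and 8 lost the call without replicates 1, 2 and 3, SNAR-A3 and HCAR3 each time. Replicate 1 correlated on average at 0.620 with the other TCP arrays and at 0.879 with FCCP replicate 1, and without the 4 arrays 2149 genes passed against control.

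**Figure D2:**
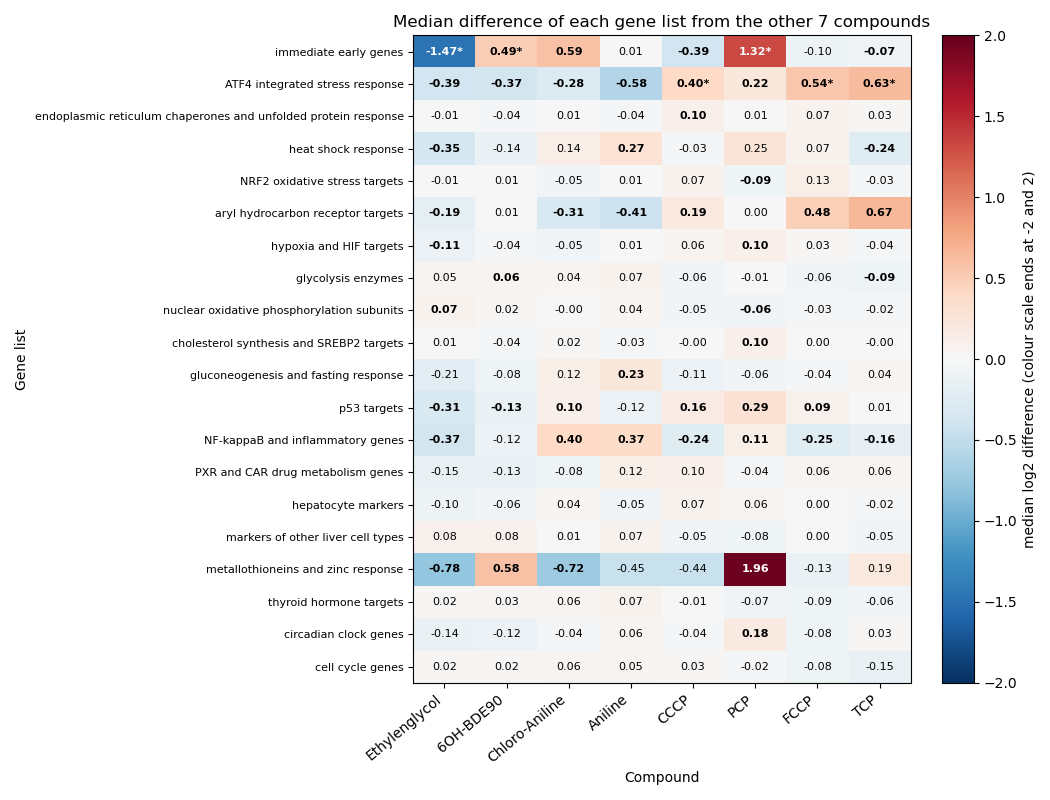
Median log2 difference of each gene list (vertical axis) between a compound (horizontal axis) and the other 7 compounds, over the measured members of the list. Bold values passed the camera test with a preset correlation, and an asterisk marks those that also passed with an estimated correlation. Immediate early genes ran from -1.47 with Ethylenglycol to 1.32 with PCP, and ATF4 targets from -0.58 with Aniline to 0.63 with TCP.

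Over all lists, 51 of 160 tests passed, 6 of them also with an estimated correlation: immediate early genes with Ethylenglycol, 6OH-BDE90 and PCP, and ATF4 targets with CCCP, FCCP and TCP. With the slide as block 52 passed, 50 of the 51 among them. Of the 51, selected by the test, 47 had medians on the same side within each slide, and 17 were lost without some array. The lists of hepatocyte markers (20 genes measured), markers of other liver cell types (5), PXR and CAR drug metabolism genes (7), thyroid hormone targets (5) and cell cycle genes (15) passed for 0 of the 8 compounds, with lowest adjusted p of 0.12, 0.12, 0.38, 0.14 and 0.25. Their medians lay between -0.15 and 0.12 in each compound. Single members passed in limma: 2 hepatocyte markers were lower with Ethylenglycol and 1 was higher with 6OH-BDE90 and with PCP. Of the other liver cells, 1 marker was higher with Ethylenglycol and with Aniline and 1 lower with PCP, and 1 cell cycle gene was lower with Ethylenglycol and 1 with TCP. Adjusted over the list alone, the marker counts did not change, the cell cycle list kept 1 (TCP). By that count 2 drug metabolism genes were higher with 6OH-BDE90, and 1 thyroid hormone target was higher with Chloro-Aniline and 1 with Aniline.

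FCCP and CCCP were compared directly as uncouplers that differ in the substituent of the phenyl ring and its place. Of the 8 genes taken by the moderated statistic, AMOTL2 differed by 0.78 (95% confidence interval 0.44 to 1.11) and KLF6 by 0.81 (0.36 to 1.25); neither passed (adjusted p = 1 for both, limma), nor did GDNF (0.54), ZNF273 (0.43), MID1IP1 (-0.40), ZNF57 (-0.36), PARP16 (-0.35) or SLC35G1 (-0.33). In limma 0 genes passed. An unadjusted p under 0.05 was reached by 345, fewer than the 917 expected by chance. The smallest adjusted p was 0.999, and the largest difference of any gene was 0.936. The 95% interval of the difference lay within 2-fold for 99.4% of genes, with a median half-width of 0.236, so differences of that size or less are not excluded, and the labels give no doses. With each of the 6 arrays left out in turn the count stayed at 0.

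Chloro-Aniline and Aniline, which differ by a chlorine, differed in 694 genes (595 higher and 99 lower with Chloro-Aniline; 36 by at least 2-fold). NEAT1 was 1.79 ± 0.36 (SE) higher with Chloro-Aniline (adjusted p = 0.0067, limma), CHAC1 1.70 ± 0.23, LIF 1.46 ± 0.12 (adjusted p = 6.3e-07), the ubiquitin ligase gene RNF19A 1.46 ± 0.13, ZNF441 1.44 ± 0.31 and GRPEL2 1.36 ± 0.27. GADD45B differed by -1.62 ± 0.30, TXNIP by -1.23 ± 0.30, ANKRD37 by -1.15 ± 0.22, METRNL by -1.08 ± 0.15, DUSP1 by -1.06 ± 0.20 and the epithelial transcription factor ELF3 by -1.02 ± 0.15, each lower with Chloro-Aniline. Of the 694 genes, selected by the test, 692 kept their direction within each slide. The count was 279 without Chloro-Aniline replicate 3, and 349 and 240 without Aniline replicates 1 and 2. TXNIP was not called without Chloro-Aniline replicate 1 (adjusted p = 0.076) or Aniline replicate 1 (0.089) or 2 (0.072). NEAT1 was lost without Chloro-Aniline replicate 3 (0.052) and ZNF441 without Chloro-Aniline replicate 3 (0.091) or Aniline replicate 1 (0.05). Averaged over its probes, NEAT1 differed by 0.76 (adjusted p = 0.09).

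PCP and TCP differed in 503 genes (378 higher and 125 lower with PCP; 65 by at least 2-fold). Higher with PCP were GADD45B by 3.38 ± 0.30 (SE, adjusted p = 2.1e-06, limma), FOS by 3.34 ± 0.44, ZFP36 by 2.35 ± 0.36, RASD1 by 2.23 ± 0.34, TXNIP by 2.20 ± 0.30 and DUSP1 by 2.20 ± 0.20. Lower with PCP were SCARNA13 (-2.24 ± 0.39), SCARNA12 (-1.84 ± 0.20), SNORA26 (-1.63 ± 0.32), SCARNA16 (-1.42 ± 0.17) and ICOSLG (-1.23 ± 0.21). SNORA12 was lower too (-2.15 ± 0.26), but dim in Cy5 on 2 of 3 PCP arrays. Of the 503 genes, selected by the test, 502 kept their direction within each slide. Higher calls made up 75.2%, 88.6% with median centring and 64.5% in the authors' processed values. The count was 253 and 222 without PCP replicates 1 and 2, and 291 without TCP replicate 2.

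Profiles of compounds were compared over all genes, each centred within its slide, and only between slides. CCCP and FCCP were the closest pair (r = 0.316 across genes, covariance 0.0092), against 0.370 and 0.195 between their own arrays. Simulated profiles without compound effects gave -0.000626 and -1.41e-05, but centring lowers r between unrelated compounds. CCCP and FCCP gave 0.518 without replicate 1 of all compounds and 0.161 without replicate 3. Then 3 pairs were closer, Chloro-Aniline and PCP the closest (0.355). Chloro-Aniline lay nearest to PCP (0.186) and then Aniline (0.112). Without replicate 1 these were 0.0988 and 0.273. CCCP and TCP gave 0.147 (0.405 without replicate 1, -0.0903 without replicate 3), 6OH-BDE90 and TCP 0.119 (-0.0844 without replicate 1, 0.302 without replicate 3), PCP and TCP -0.00141 (0.195 and -0.139 likewise), and Ethylenglycol and PCP were the most opposed (-0.439). Genes are not independent replicates, so these values carry no p. The uncentred profiles over control correlated at 0.885 (FCCP and CCCP), 0.739 (Chloro-Aniline and Aniline) and 0.699 (PCP and TCP). Dye effects and control RNA enter both sides, and no chance value is known.

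The control channel varied little between the arrays of different compounds. After normalization between arrays, 3 genes differed in Cy3 between the 8 groups of arrays (limma, 586 at an unadjusted p under 0.05), and 9 with the slide as block, against 2952 genes in Cy5 (5133 with the slide as block). In the log ratios 4784 genes differed between compounds in an F-test.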

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

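The 2 results below were picked out because a test of the difference between compounds of related names was itself significant, as planned before the data were examined.

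Chloro-Aniline and Aniline differed in 694 genes (limma, 595 higher and 99 lower with Chloro-Aniline), led by NEAT1, CHAC1 and LIF on the higher side and GADD45B and TXNIP on the lower. The 10 ways of dividing these 6 arrays into groups of 3 are too few for a share under 0.05. The real division gave 694 genes, the highest other gave 0, and 1 of 10 reached the real count. The count was 240 and 349 without Aniline replicates 2 and 1, and 279 without Chloro-Aniline replicate 3.

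PCP and TCP differed in 503 genes (limma, 378 higher and 125 lower with PCP), with GADD45B, FOS and DUSP1 higher and 5 small nucleolar or Cajal body RNAs lower. Here, too, 10 divisions of 6 arrays are too few for a share under 0.05: the real one gave 503 genes, the highest other gave 1, and 1 of 10 reached the real count. The count was 222 and 253 without PCP replicates 2 and 1, and 291 without TCP replicate 2. The doses of the compounds are not in the labels, and no explanation of either difference was tested.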

How the results depend on the processing

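One alternative was chosen after the results were seen: leaving out together the 4 arrays named in the Results. Over the alternatives, values of named genes kept their direction and their side of the threshold in 7339 cases, lost significance in 644, gained it in 113 and reversed in 19; list calls held in 381 cases and were lost in 78. Unless a reason is given, the cause was not tested. Signal over background limited which genes were tested, 32462 with no filter and 14389 with the stricter one.

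The replicate number as block changed counts of calls against the other compounds to 276 for 6OH-BDE90 (from 177), the control channel to 9 (from 3) and the Cy5 channel between compounds to 5133 (from 2952); no other count moved by over 1.5 times. The numbers mark slides, and the labels name no shared batch or day. The arrays were not treated as paired: same-numbered arrays of 2 compounds correlated at 0.0822 on average (-0.505 to 0.801; -0.0387 for different numbers), all 3 correlations exceeded 0.1 in 8 of 28 pairs of compounds, and 10 of 24 arrays lay closest to their own number.

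Median centring shifted the median of all genes over control by 0.141 (Ethylenglycol), 0.372 (Chloro-Aniline), 0.192 (Aniline), 0.306 (CCCP), 0.313 (PCP), 0.192 (FCCP), 0.179 (TCP) and 0.223 (mean of the 8), against the other compounds by -0.151 (6OH-BDE90) and 0.170 (Chloro-Aniline), and by -0.115 (FCCP minus CCCP) and 0.151 (Chloro-Aniline minus Aniline). It gave 11330 (Chloro-Aniline), 9290 (CCCP) and 9048 (PCP) calls against control, 1936 (Ethylenglycol), 919 (Chloro-Aniline), 1281 (Aniline), 96 (CCCP), 91 (FCCP) and 78 (TCP) against the other compounds, 334 for PCP minus TCP and 1 in the control channel; this shift of all genes by construction raises the share of higher calls against control. POLR2A over control with Chloro-Aniline reversed to 0.05.

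The scanner software's processed signals gave 284 (Chloro-Aniline) and 229 (FCCP) against the other compounds, 458 for Chloro-Aniline minus Aniline and 329 for PCP minus TCP. The mean over probes gave 1 gene in the control channel. Only the comparison's own arrays, with fewer samples for the spread, gave 2889 (Chloro-Aniline), 1230 (FCCP) and 1381 (TCP) against control, 259 for Chloro-Aniline minus Aniline and 240 for PCP minus TCP; higher calls were 71.4% (FCCP) and 68.7% (TCP). Array weights gave 4868 (Ethylenglycol), 1751 (6OH-BDE90), 2124 (Chloro-Aniline), 5650 (Aniline), 310 (CCCP), 2470 (PCP), 1719 (FCCP) and 3955 (TCP) against the other compounds. The authors' processed values gave 301 (CCCP), 384 (Chloro-Aniline minus Aniline), and 50.4% higher calls for Ethylenglycol against the other compounds. Cy5 alone gave 70 (6OH-BDE90), 200 (Chloro-Aniline), 1501 (Aniline), 85 (CCCP), 840 (PCP), 188 (FCCP) and 179 (TCP), and 47% (Chloro-Aniline) and 77.7% (CCCP) higher calls. An estimated correlation left 6 of the 51 lists. A fold of at least 2 left, by its construction, 116, 88, 116, 228, 76, 227, 103 and 110 genes against control in the order Ethylenglycol, 6OH-BDE90, Chloro-Aniline, Aniline, CCCP, PCP, FCCP and TCP, and 148, 14, 10, 82, 8, 87, 10 and 17 against the other compounds. Without the 4 arrays, TCP had 2149 calls against control, and 6OH-BDE90 had 275, Chloro-Aniline 1206, CCCP 303 and FCCP 629 against the other compounds.

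With Ethylenglycol as the reference, counts were 1190 (6OH-BDE90), 2324 (Chloro-Aniline), 2010 (CCCP), 3479 (PCP), 2224 (FCCP) and 2086 (TCP). All reversals but that of POLR2A come from this choice, as Ethylenglycol was itself low in these genes: FAM59A 0.09, CTH 0.04, DDIT4 0.39 and BBC3 0.02 (6OH-BDE90), HEXIM1 0.05, DDIT4 0.51 and ASNS 0.05 (Chloro-Aniline), TIPARP 0.05 and PPP1R15A 0.16 (Aniline), CCL20 0.24, EDN1 0.77, FOS 1.05, IER3 1.04 and CYR61 1.51 (CCCP), SGK1 0.51 and CCL20 0.27 (FCCP), FOS 0.97 and DUSP1 2.48 (TCP).

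Leaving out each array in turn gave, against control, 2834 to 4116 (Ethylenglycol), 2453 to 3778 (6OH-BDE90), 2893 to 4777 (Chloro-Aniline), 4654 to 6024 (Aniline), 1793 to 2463 (CCCP), 3733 to 4049 (PCP), 2686 to 3760 (FCCP) and 1674 to 4595 (TCP); against the other compounds 1699 to 2075, 16 to 39, 17 to 1010, 1300 to 1774, 15 to 100, 650 to 1078, 52 to 381 and 64 to 289 in that order; 240 to 945 for Chloro-Aniline minus Aniline, 222 to 519 for PCP minus TCP and 0 for FCCP minus CCCP each time. Against control the lowest count came without replicate 2 for the first 4 compounds and without replicate 1 for the last 4. The first 4 lay at array positions 1_1 to 1_4 and the last 4 at 2_1 to 2_4. Against the other compounds the lowest count came without replicate 2, except for FCCP (replicate 3). Leaving out a whole slide gave 10305 to 11396 for the mean of the 8, 0 to 3 for the control channel, 45 to 59 lists, and 0.1612 to 0.5176 for the correlation of CCCP and FCCP.

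Regrouping the 24 arrays 100 times reached each count against the other compounds with a share under 0.05: Ethylenglycol 2967 (highest other 239, reached by 1 of 100 including the real grouping), Aniline 2526 (913; 1), PCP 1462 (1128; 1), TCP 296 (16; 1), CCCP 153 (437; 2), FCCP 359 (854; 2), 6OH-BDE90 177 (245; 3) and Chloro-Aniline 528 (1909; 3). The 1909 came from a grouping of the 3 Ethylenglycol arrays and 437, 854 and 245 from groupings with 1 or 2 of these arrays, but groupings without them also exceeded the real count: 1141 for Chloro-Aniline (6OH-BDE90 2, Aniline 2 and TCP 1) and 227 for 6OH-BDE90 (Aniline 3, Chloro-Aniline 2 and 3). The arrays thus hold a structure beyond the compounds. With compounds shuffled only within slides, a test added after the results were seen, 1 or 2 of 100 groupings reached the real count (highest other 102, 322, 121, 309, 4, 585, 237 and 1222 in that order). All compounds were shuffled at once, so no single count is decided, and the structure stays open. The control channel (3; highest other 1; 1 of 100) and the lists (51; highest other 50; 1 of 100) passed as well, but the median of regrouped arrays was 33 lists. For FCCP minus CCCP the 10 divisions of 6 arrays are too few for a share under 0.05: the real count was 0, the highest other 1, and 10 of 10 reached it.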

Other observations

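In this part the tests with arrays left out, of the tubulin genes, of a dye or control effect of the same size on every array, of array position and of labelling were chosen after the results were seen, whereas the test on second probes was written before. TXNIP, ARRDC4, CYP1A1 and the small RNAs below were picked after their values were seen.

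TXNIP, a binding partner of thioredoxin that responds to glucose, divided the exposures. It rose over control with Aniline (1.81 ± 0.15, SD, n = 3, log2), PCP (1.73 ± 0.19), Ethylenglycol (1.23 ± 0.16) and Chloro-Aniline (0.59 ± 0.98) and fell with FCCP (-1.20 ± 0.36) and CCCP (-0.91 ± 0.32), while 6OH-BDE90 (-0.54 ± 0.30) and TCP (-0.47 ± 0.13) missed the test in limma. Its relative ARRDC4 rose with Ethylenglycol (1.33 ± 0.14), PCP (0.92 ± 0.27), Aniline (0.90 ± 0.15) and Chloro-Aniline (0.61 ± 0.67), and was lower with FCCP and CCCP than with the other compounds, by -0.83 and -0.76 (SE 0.17 each). CYP1A1, a monooxygenase, fell over control with Aniline (-3.21 ± 0.18), Ethylenglycol (-2.66 ± 0.15), Chloro-Aniline (-2.07 ± 0.95), 6OH-BDE90 (-1.10 ± 0.13), FCCP (-0.81 ± 0.51) and CCCP (-0.69 ± 0.43). With PCP (-0.14 ± 0.34) and TCP (-0.16 ± 0.17) it missed that test, and there it lay 1.39 and 1.36 (SE 0.24 each) above the other compounds. Chloro-Aniline replicate 1 stood at -0.55 (TXNIP) and -0.10 (ARRDC4); the means were 1.15 and 0.97 without it, and missed the test without replicate 2 (0.34 and 0.57) or 3 (0.27 and 0.30). Without replicate 1, TXNIP with CCCP (-0.76) and CYP1A1 with CCCP (-0.48) and FCCP (-0.55) missed it too, as did CYP1A1 with CCCP without replicate 2 (-0.69).

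The small Cajal body RNA SCARNA13 stood at -2.66 ± 0.19 over control with Aniline, -2.65 ± 0.11 with PCP and -2.30 ± 0.60 with Chloro-Aniline, and SNORA12 at -1.54 ± 0.02, -2.54 ± 0.15 (exposed signal well above background on 1 of 3 arrays) and -1.54 ± 0.55 (SD, n = 3). With Ethylenglycol they stood at 0.20 ± 0.38 and 0.43 ± 0.47, which missed the test against control in limma, and lay 1.74 ± 0.29 and 1.58 ± 0.20 (SE) above the other compounds. Both also fell with 6OH-BDE90 (-1.25 ± 0.23 and -0.96 ± 0.36) and CCCP, whose arrays differed more (-0.94 ± 0.99 and -0.76 ± 0.45), while FCCP (-0.56 ± 0.81 and -0.33 ± 0.14) and TCP (-0.41 ± 0.42 and -0.39 ± 0.43) missed the test. With CCCP neither passed without replicate 1 (-0.42 and -0.56) or 2 (-1.01 and -0.72), and SNORA12 with Ethylenglycol passed without replicate 1 (0.70).

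Tubulin genes were lower with CCCP and FCCP. Over all 15 alpha and beta tubulin genes the median difference from the other compounds was -0.48 with CCCP and -0.42 with FCCP (8 genes called lower in limma with each), and it stayed below 0 with median centring (-0.41 and -0.51, though only 1 and 4 were called), with the scanner software's processed signals (-0.48 and -0.43) and with the mean over probes (-0.37 and -0.34), while it was 0.31 with Ethylenglycol, 0.21 with Aniline and between 0.02 and 0.13 with the other 4 compounds. Signal shared between near-identical tubulin probes stays open: over the 10 tubulins not named in the report, whose probes share no sequence with those of the named ones, the medians were -0.312 (95% bootstrap interval -0.493 to -0.0512) and -0.145 (-0.427 to -0.0169), and the upper ends of the intervals lie near 0. As a hypothesis, tubulin transcripts may fall as a class with these uncouplers, with 4 of the 10 called lower in each. Of 10000 random gene sets of the same size and brightness, 0 had a median as low with either. Such sets take genes as independent and hold no spread between arrays. The tubulin set was narrowed to alpha and beta genes after a wider set of 25 had been seen (medians -0.21 and -0.14), so it is not independent of the pattern.

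The 66 genes changed by at least 2-fold in the mean of the 8 exposures had no dye swap behind them. Of these genes 97% differed between compounds, against 26.1% of all genes. A dye or control effect of the same size on every array cannot account for those differences. The test is unchanged by such an effect, so how much of the mean ratio it makes up stays open. A dye effect of single probes stays open: 8 of the 66 genes had a second probe without shared sequence, whose median was 0.839 in the direction of the first probe (first probes 1.2), 7 of 8 on the same side. The bootstrap interval of that median, added after the value was seen, was 0.0637 to 1.58, so that these 8 genes cannot separate the explanations.

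The distance of Ethylenglycol from the other compounds could come from its fixed array position. An effect of position on both channels is argued against by the control channel, where 3 genes differed between the Ethylenglycol arrays and the others, against 2004 in Cy5. Weak labelling of the exposed RNA is argued against by 32848 Cy5 spots well above background on average (SD 966 over 3 arrays), within the 31566 to 34686 of the other compounds. An effect of position on Cy5 alone, the dose and the compound itself stay open. Of the 116 genes changed by at least 2-fold with Ethylenglycol, 25 had a second probe, with 23 on the same side and a median of 0.538 against 1.2 for the first.

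Across genes, the log ratios of FCCP replicate 1 correlated at 0.879 with TCP replicate 1 and at 0.826 with 6OH-BDE90 replicate 2, and those of the last 2 at 0.817 with each other. On average they correlated less with the other arrays of their own compound (0.514, 0.620 and 0.76), and 0.879 was the highest between any 2 arrays.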
